A study of Mus musculus with 24 samples.

How the data were processed

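NK cells were profiled by bulk RNA sequencing of poly(A) RNA in 24 mouse libraries: 16 from spleen and 8 from tumour-bearing lung, in 6 groups of 4. The groups cross genotype (WT, or KO of FcRγ) with naive spleen, IL-15-treated spleen and tumour-bearing lung. Per the labels' protocols, RNA was taken up with the Qiagen RNeasy Plus Micro kit and libraries were made with the NEBNext Ultra II Directional kit after poly(A) enrichment. The labels call the 4 libraries of a group biological replicates. Whether each is a separate animal, how IL-15 was given and which tumour was used are not given in the sources used here, so p-values measure spread between samples the labels call biological replicates.

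The deposited table holds expected counts from RSEM, 38215 genes by 24 libraries. Per the submitters' processing notes, cutadapt 1.9, STAR 2.5.2a, RSEM 1.2.30 and the GRCm38 genome were used; their order, settings and annotation release are not given in the sources used here. Of the deposited expected counts 5.47% were not whole numbers, and 290 symbols were shared by more than 1 gene. Totals per library ranged from 9.68 to 32.10 M counts: 24.58 to 32.10 in naive WT, 9.68 to 27.46 in naive KO, 21.18 to 30.55 in IL-15 WT, 23.67 to 30.20 in IL-15 KO, 9.77 to 26.98 in lung WT and 24.95 to 26.75 in lung KO. Between 12456 and 16000 genes had a read, and no library repeated another.

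Counts were rounded and analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood F test), with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05 on the adjusted p. All p-values for genes are from edgeR and adjusted unless named otherwise. Spleen libraries were fitted together, lung libraries together, and all 24 together for lung against spleen. The 9 comparisons were KO against WT in each of the 3 states, IL-15 against naive and lung against naive spleen in each genotype, and the difference of the KO effect between naive and IL-15 and between naive and lung, each tested as an interaction. Standard errors are the log2 change divided by the root of F. Levels are CPM on TMM-scaled totals, and a prior count of 2 was used for log CPM in the principal components and library profiles. Where every library of a group had 0 counts, a bound is given against a floor of 3 counts over the group.

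Before the data were examined, 25 gene lists, 15 marker lists, the comparisons, most of the alternatives and the rule for named genes were fixed. The gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over lists within a comparison, and again with an estimated correlation. Adaptors, Ly49 receptors, ITAM signalling, granule genes, cytokines, mature, immature and ILC1 genes, STAT5 response, mitosis, quiescence, glycolysis, oxidative phosphorylation, MYC targets, nutrient transport, sterol synthesis, dysfunction, interferon, TGFβ, immediate early genes, trafficking, transcription factors, neighbours of Fcer1g, sex-linked and mitochondrial genes were covered. Marker lists were summed as CPM and compared with exact permutation tests, whose smallest possible p at 4 against 4 is 0.0286. Named genes were Fcer1g, the 8 largest changes each way among genes that passed with a mean of at least 1 CPM and no overlap of libraries (overlap not used for interactions, predicted genes and antigen receptor segments skipped). The rule added up to 3 genes per list by smallest p, and all genes where 30 or fewer passed. Some of these genes are not reported here. The text prints part of the genes this rule gives, picked for readability after their values were seen; how many of all of them kept their call is given for each KO comparison and each interaction.

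Union exon lengths and GC content came from GENCODE M21 for 98.6% of tested genes. On data simulated from these counts the test recovered 21.2, 61.5 and 82.8% of genes changed 1.5-, 2- and 4-fold in naive KO against WT. The shares were 25.8, 62.7 and 77.8% under IL-15, and 12.3, 66.2 and 92.1% in lung, with 1.8 to 3.5% false calls. The simulation drew each gene independently at its fitted spread, without a length trend or libraries that deviate beyond their totals. Its shares may therefore not carry over to the real libraries. Alternatives were DESeq2 1.42.0, its size factors in edgeR, voom with library weights, no filter and a stricter filter, a length and GC offset, removal of mitochondrial genes, fits of the compared groups alone or of all 24 libraries, a block by replicate number or, for IL-15 against naive, by library number, and each library left out in turn. Voom with library weights, the length and GC offset and removal of mitochondrial genes were not among the alternatives fixed before the data were examined. Leaving out the shallow libraries together was added after the data were seen. No sample was left out of the main fits.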

Results

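Fcer1g encodes FcRγ, the signalling adaptor that carries an ITAM and pairs with CD16 and NKp46 in NK cells. Fcer1g stood at 730 ± 78.8 CPM (mean ± SD, n = 4 libraries) in naive WT spleen, 274 ± 31.7 in IL-15-treated WT spleen and 595 ± 115 in WT tumour-bearing lung. In the KO libraries it stood at 3.77 ± 2.37, 5.65 ± 1.84 and 14.3 ± 1.61 CPM, or 0.52, 2.06 and 2.40% of the WT mean. The lowest WT library held 253 CPM and the highest KO library 16.2 CPM, so the gene separated all 24 libraries by genotype. The KO effect on Fcer1g was −7.54 ± 0.35 log2 units (± standard error) in naive spleen, −5.61 ± 0.31 under IL-15 and −5.38 ± 0.17 in lung, with adjusted p values of 1.71e-10, 2.93e-09 and 1.05e-08. On principal components of all 24 libraries, the leading component held 35.7% of the variance and the next 25.5%. On component 3 (7.4%) KO naive replicate 1 stood alone at −135.0, with the others between −13.6 and 35.3, and on component 4 (5.2%) WT lung replicate 1 stood at 88.8, with the others between −37.2 and 49.7.

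**Figure D1:**
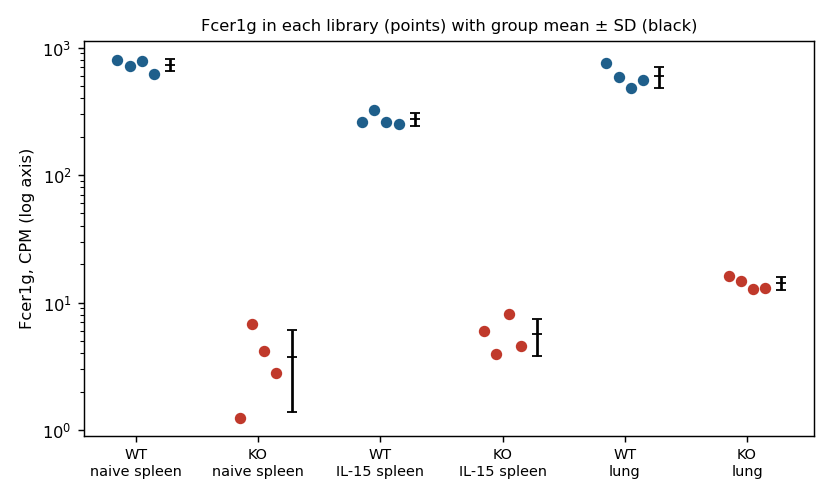
Each point is 1 library, with Fcer1g in CPM on a log axis and the 6 groups side by side. WT libraries ranged from 253 to 795 CPM and KO libraries from 1.25 to 16.2 CPM.

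In naive spleen, transcripts of Fcgr2b and of several protein chaperones were lower in KO, and those of Socs2, Rrp12 and Fasn were higher. Fcgr2b, the inhibitory Fc receptor for IgG, encoded near Fcer1g, fell by 2.35 ± 0.25 log2 units (5.75 ± 1.51 against 28.8 ± 2.11 CPM, n = 4 and 4, adjusted p = 1.62e-05). The chaperones Hsph1 (−2.48 ± 0.25, 46.8 ± 19.6 against 254 ± 93.4 CPM, adjusted p = 9.57e-06), Hspa8 (−1.56 ± 0.17) and Dnaja1 (−1.55 ± 0.18) fell, as did the chemokine Ccl6 (−3.0 ± 0.54, adjusted p = 0.00108). Socs2, a feedback inhibitor induced by STAT5, rose by 1.28 ± 0.20 and the lysosomal trafficking regulator Lyst by 1.37 ± 0.28. With edgeR, 1475 genes were higher and 1230 lower in KO among 13344 tested, and 481 and 122 of these changed by at least 2-fold.

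Of 25 tested adaptors and partner receptors of the FcRγ, CD3ζ and DAP12 list, 1 rose and 9 fell (list adjusted p = 2.07e-07, and adjusted p = 0.718 with an estimated correlation). The list holds Fcer1g itself, the deleted gene, and its neighbours Fcgr2b, Cd244 and Slamf6, so its counts and tests between genotypes include them. Cd244, a receptor for CD48 encoded near Fcer1g, was among those that fell (−0.83 ± 0.10, adjusted p = 4.02e-05). Among 47 nuclear genes of oxidative phosphorylation 17 fell and none rose (list adjusted p = 1.16e-06, and adjusted p = 0.718 with an estimated correlation). Atp5c1 fell by 0.64 ± 0.12, Cox7a2 by 0.66 ± 0.15 and Ndufa9 by 0.57 ± 0.13. Of 35 MYC targets and ribosome biogenesis genes 10 rose and 3 fell (list adjusted p = 0.0398, and adjusted p = 0.718 with an estimated correlation). Rrp12, which acts in ribosomal subunit maturation, rose by 1.09 ± 0.20 and Nolc1, a nucleolar protein gene, by 0.98 ± 0.15. In cholesterol and fatty acid synthesis 7 of 30 genes rose and 2 fell (list adjusted p = 0.0985). Fasn, the fatty acid synthase gene, rose by 1.10 ± 0.17, Hsd17b7, encoded near Fcer1g, by 1.32 ± 0.22 and the sterol regulator Srebf2 by 0.79 ± 0.13. In the cytotoxic granule and death ligand list 2 rose and 7 fell of 26, where Serpinb9 (−0.92 ± 0.17) and Serpinb6b (−0.97 ± 0.18), inhibitors of proteases, were among those that fell (list adjusted p = 0.142).

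Among interferon-stimulated genes 1 rose and 8 fell of 39 (list adjusted p = 0.142), including the GTPases Ifi47 (−0.68 ± 0.12, adjusted p = 0.000813) and Irgm1 (−0.55 ± 0.13). Of 11 Ly49 receptors 1 rose and 3 fell, with Klra8 (Ly49H) at −1.0 ± 0.15, Klra4 (Ly49D) at −0.95 ± 0.18 and Klra6 at 0.56 ± 0.15 (list adjusted p = 0.142). The Klra genes resemble each other in sequence, so their separate values are uncertain. Of 48 mitotic and S phase genes 2 rose and 13 fell (list adjusted p = 0.183). NK cell transcription factors held 6 that rose and 2 that fell of 34, with Ikzf2 (Helios) at 1.34 ± 0.27, Bach2 at 1.02 ± 0.17 and Rora at 1.01 ± 0.18 (list adjusted p = 0.183). The ILC1 and tissue residency list held 6 that rose and none that fell of 25, with Tmem176a at 1.34 ± 0.25 (list adjusted p = 0.171). The immediate early and heat shock list moved both ways, with 4 that rose and 7 that fell of 33, a median of 0.10 and a mean of −0.10 (list adjusted p = 0.377, direction of the test down). None of 15 mitochondrially encoded genes and none of 5 sex-linked genes passed, and 10 of 52 neighbours of Fcer1g on chromosome 1 rose while 9 fell.

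Long transcripts were higher in the naive KO libraries: genes with at least 10 kb of exons had a median change of 0.30 (n = 903) and those under 1.5 kb a median of −0.35 (n = 553). The mitochondrial share of reads was 5.85 ± 3.86% in naive KO and 5.41 ± 0.63% in naive WT (exact p = 0.914), with KO naive replicate 1 at 1.18% and the other KO libraries between 4.19 and 9.28%. KO naive replicate 1 held 9.68 M counts against 23.30 to 27.46 M in the other naive KO libraries. Gzma, a granule protease, passed at −0.53 ± 0.16 but stood at 0.02 (adjusted p = 0.963) after a length and GC correction and at −0.46 (adjusted p = 0.0764) without KO naive replicate 4, 1 of the 3 libraries of 8 whose removal ended its call. Without WT naive replicate 3 the counts were 942 higher and 755 lower. Of the 74 genes the naming rule gave that passed here, 55 kept their call in every alternative; the receptor Klrg1 (−0.44 ± 0.14) was among the 19 that did not, with −0.30 (adjusted p = 0.14) without WT naive replicate 4. Its call ended with 6 of 8 libraries left out in turn and with the length and GC correction (adjusted p = 0.582) or the compared groups fitted alone (0.0667).

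Under IL-15 only 18 genes differed between KO and WT, 11 higher and 7 lower, at n = 4 and 4 and the same 13344 genes tested. Apart from Fcer1g, the largest falls were in members of the HIN-200 and pyrin domain family on chromosome 1: Gm4955 (−5.43 ± 0.21), Pydc4 (−3.81 ± 0.31), Pydc3 (−2.47 ± 0.30) and Pyhin1 (−2.33 ± 0.20). Ifi204 of the same family rose by 2.05 ± 0.33. Slamf6, a homotypic receptor of lymphocytes, rose by 1.47 ± 0.18 (adjusted p = 0.000147), Sh2d1b2 (EAT-2B), an adaptor of SLAM receptors, by 2.03 ± 0.20, and Cd244, another SLAM receptor, fell by 0.82 ± 0.10 (adjusted p = 0.000147). Itln1, which encodes an intelectin, stood at 10.7 ± 4.85 CPM in KO (8.51 ± 0.83), and Prrc1, a protein of the secretory pathway, rose from 43.9 ± 3.81 to 96.2 ± 7.58 CPM (1.12 ± 0.12, adjusted p = 6.99e-05).

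Also higher were Gm4724 (5.48 ± 0.90), Gm8923 (4.28 ± 0.69), Fcrl6 (1.46 ± 0.27) and Srp54b (0.89 ± 0.10), with Hist1h4m and Ifi202b. These last had no read in WT and were at least 37.9-fold and at least 22.6-fold higher in KO. Reads of the HIN-200 family, Gm4724 and Gm8923, Hist1h4m, Srp54b, Itln1 and Sh2d1b2 can be shared with near-identical copies, so the values of these genes are uncertain. No gene of the Ly49 list passed among 11 (list adjusted p = 4.93e-05, and adjusted p = 0.566 with an estimated correlation; adjusted over the list alone, 2 fell). In the adaptor list 1 rose and 2 fell of 25 (adjusted p = 0.0138, and adjusted p = 0.726 with an estimated correlation). Slamf6 was the member that rose, and those that fell were Cd244 and the deleted Fcer1g. In the proximal ITAM and calcium signalling list 1 of 40 rose (adjusted p = 0.00876, and adjusted p = 0.673 with an estimated correlation). None of 47 oxidative phosphorylation genes passed (adjusted p = 0.000216, and adjusted p = 0.726 with an estimated correlation). Neither did any of 33 IL-15 and STAT5 response genes (adjusted p = 0.00533, and adjusted p = 0.0506 with an estimated correlation). None of 23 nutrient transporters and mTORC1 targets passed (adjusted p = 0.0186, and adjusted p = 0.618 with an estimated correlation). DESeq2 gave 20 higher and voom with library weights 30 higher and 24 lower, and without WT IL15 replicate 3 edgeR gave 7 higher. With each of 8 libraries left out in turn, the call ended 8 times for Ifi202b, 7 times for Fcrl6, 4 times for Hist1h4m and 1 time for Gm4724. The largest adjusted p was 0.125, 0.13 and 0.0614 for the first 3, without WT IL15 replicate 4, and 0.054 for Gm4724, without WT IL15 replicate 3. A block by replicate number also ended the call for Ifi202b (0.243), Hist1h4m (0.103) and Fcrl6 (0.0532). Of the 18 genes, 13 kept the call throughout.

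In tumour-bearing lung, KO NK cells had more transcript of the IL-7 receptor and less of several chaperones. Il7r, the IL-7 receptor chain found on ILC1 and immature NK cells, rose from 24.7 ± 3.95 to 69.8 ± 16.8 CPM (1.49 ± 0.18, n = 4 and 4, adjusted p = 0.00205). Socs2 rose by 1.16 ± 0.17 and Slamf6 by 2.27 ± 0.23. The chaperone adaptor Stip1 fell from 442 ± 100 to 163 ± 30.1 CPM (−1.44 ± 0.18, adjusted p = 0.00235). The chaperone genes Hsp90aa1 (−1.21 ± 0.15), Hspd1 (−1.09 ± 0.12), Dnaja1 (−1.0 ± 0.13) and Hsph1 (−1.87 ± 0.28, adjusted p = 0.00646) fell with it. Fcgr2b fell by 3.51 ± 0.15 (adjusted p = 7.7e-08) and the phosphatase gene Bpnt1 by 1.43 ± 0.15. In all, 40 genes were higher and 42 lower of 13129 tested with edgeR.

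Of 33 immediate early and heat shock genes 6 fell and none rose (adjusted p = 4.27e-07, and adjusted p = 0.153 with an estimated correlation). In the ILC1 and tissue residency list 3 of 25 rose (Il7r, Ahr and Cd3g) and none fell (adjusted p = 2.51e-05, and adjusted p = 0.173 with an estimated correlation). Il7r and Cd3g are also read in T cells, whose summed markers stood at 414 ± 53.8 CPM in KO and 344 ± 46.3 in WT (exact p = 0.0857, adjusted p = 0.297). In the immature NK cell list 2 of 21 rose, Il7r and Kit (0.71 ± 0.12; list adjusted p = 7.98e-05, and adjusted p = 0.193 with an estimated correlation). Of 15 mitochondrially encoded genes 5 rose and none fell, with mt-Co1 at 1.08 ± 0.19 and mt-Rnr2 at 0.85 ± 0.16 (adjusted p = 3.49e-26, and adjusted p = 0.153 with an estimated correlation). The mitochondrial share of reads was 9.18 ± 1.05% in KO and 4.74 ± 1.22% in WT (exact p = 0.0286, 1 of 3 such tests). None of 48 mitotic and S phase genes passed, though the list test pointed down (adjusted p = 1.33e-06, and adjusted p = 0.265 with an estimated correlation). None of 41 interferon-stimulated genes passed, with the list test pointing up (adjusted p = 0.000734, and adjusted p = 0.348 with an estimated correlation). In the adaptor list 1 of 26 rose and 3 fell (adjusted p = 2.95e-06, and adjusted p = 0.348 with an estimated correlation). Slamf6 was the member that rose, and those that fell were Cd244, Fcgr2b and the deleted Fcer1g.

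Genes with at least 10 kb of exons had a median change of 0.114 in lung KO and those under 1.5 kb a median of −0.177. WT lung replicate 1 held 9.77 M counts against 24.73 to 26.98 M in the other WT lung libraries, and without it the counts were 251 higher and 197 lower (16 and 25 without KO lung replicate 2). Hsph1 stood at −1.81 (adjusted p = 0.0517), Kit at 0.62 (0.109) and mt-Co1 at 0.97 (0.132) without KO lung replicate 2. Ahr stood at 0.80 (0.164), Cd3g at 1.21 (0.148) and mt-Rnr2 at 0.82 (0.165) without KO lung replicate 4. With each of 8 libraries left out in turn, the call ended 7 times for Cd3g, 6 times for Ahr and Kit, 5 times for mt-Co1 and mt-Rnr2 and 1 time for Hsph1. It also ended with all 24 libraries fitted for Cd3g (0.0577), Kit (0.0599), mt-Co1 (0.288) and mt-Rnr2 (0.163), and with the length and GC correction for Kit (0.0516). A block by replicate number ended it for Ahr (0.0521), Cd3g (0.12), Kit (0.0556) and mt-Rnr2 (0.0699). Of 28 named genes 17 kept their call in every alternative.

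The KO and WT comparisons of the 3 states share no library. In each genotype 3 naive and 3 IL-15 libraries carry the same number in their names, and whether they share animals is not given in the sources used here, so the overlaps given as if independent assume separate animals. Of the 11 genes higher in KO under IL-15, 10 were higher in naive spleen too (1.22 if independent), and all 7 lower genes were lower there (0.65 if independent). Between naive spleen and lung, 24 genes were higher in both and 41 lower in both (4.41 and 4.08 if independent). Across the 3 comparisons, 14 genes were called in all 3 states, each in the same direction.

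Many of these genes lie beside Fcer1g, which spans 171229572 to 171234365 on chromosome 1 (GRCm38). Within 10 Mb of it, 12 of 158 tested genes passed under IL-15 (7.6%) against 5 of 13185 elsewhere (0.04%), an odds ratio of 215.03 (95% interval 69.66 to 801.30, Fisher exact p = 2.93e-20). In lung 14 of 153 passed near Fcer1g (9.2%) against 67 of 12975 elsewhere (0.52%), an odds ratio of 19.38 (9.82 to 35.86, Fisher exact p = 4.35e-13). In naive spleen the shares were 49 of 158 (31.0%) against 2655 of 13185 (20.14%), an odds ratio of 1.78 (1.24 to 2.53, Fisher exact p = 0.00134). The genes called under IL-15 or in lung included Ifi202b, at 2.73 Mb, Slamf6, Cd244, Sh2d1b2, Pyhin1 and Pydc4. Prrc1, which passed in all 3 states, lies on chromosome 18 (57354733 to 57392719).

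**Figure D2:**
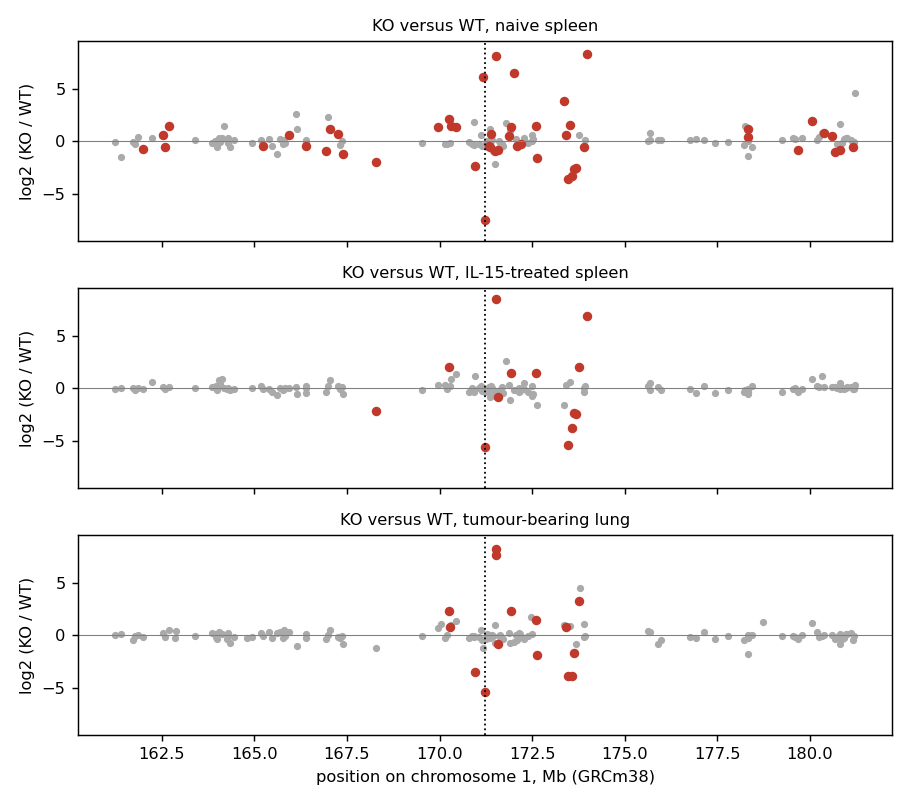
Each point is 1 tested gene within 10 Mb of Fcer1g, Fcer1g included. Its position on chromosome 1 in Mb (GRCm38) runs across and its log2 change, KO against WT, upward, for the 3 states. A dotted line marks Fcer1g. Genes that passed are marked. Besides Fcer1g, 12 of 158 passed under IL-15 and 14 of 153 in lung.

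IL-15-treated WT spleen NK cells had higher transcripts of cell division, sterol synthesis and glycolysis genes than naive ones, and lower transcripts of mature circulating NK cell genes. The sources used here do not say whether naive cells were handled in the same way. IL-15 and any difference in preparation thus cannot be told apart here. Spp1, which encodes osteopontin, rose from 4.31 to 522 ± 59.9 CPM (6.83 ± 0.20, n = 4 and 4, adjusted p = 7.74e-14), and the granzyme gene Gzmc rose by 6.35 ± 0.42. The squalene epoxidase gene Sqle rose by 5.39 ± 0.24, the glycolytic enzyme gene Aldoc by 5.92 ± 0.20 and the mitotic kinesin gene Kif11 by 4.19 ± 0.16. Klf2, a transcription factor that supports lymphocyte recirculation, fell by 4.92 ± 0.19, and its companions in egress, the sphingosine phosphate receptor genes S1pr5 and S1pr1, fell by 4.24 ± 0.15 and 4.25 ± 0.22. Cma1, a mast cell type protease gene also read in mature NK cells, fell by 5.71 ± 0.22, and Tbx21 (T-bet) fell by 2.54 ± 0.14. In all 3526 genes were higher and 3468 lower in WT, and 2138 and 936 of these changed by at least 2-fold.

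The same comparison in KO spleen gave 2766 higher and 2798 lower genes. Spp1 stood at 6.96 ± 0.21, Gzmc at 6.47 ± 0.43, Sqle at 5.94 ± 0.26, Aldoc at 5.95 ± 0.20 and Kif11 at 4.22 ± 0.16. Klf2 stood at −4.63 ± 0.19, S1pr5 at −4.16 ± 0.14, Cma1 at −6.13 ± 0.23 and Tbx21 at −2.31 ± 0.14. Across the 13344 tested genes the change in KO correlated with that in WT at r = 0.789 (0.879 over the genes called in WT), with the same sign in 82.2% of genes. Of the calls, 2295 were higher in both genotypes (730.88 if independent) and 2236 lower in both (727.18 if independent), while 6 genes rose in WT and fell in KO and 11 did the opposite.

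All 48 mitotic and S phase genes rose in both genotypes (adjusted p = 1.49e-70 in WT and 1.66e-100 in KO). Cholesterol and fatty acid synthesis genes rose in 26 of 30 in WT with 1 that fell (adjusted p = 1.94e-22), and in 24 with 1 that fell in KO (adjusted p = 4.9e-23). Of 22 glycolysis genes 18 rose in WT and 19 in KO, and none fell (adjusted p = 0.00348 and 0.00193 with an estimated correlation), including the lactate transporter gene Slc16a3 (3.43 ± 0.15 in WT) and Pgk1 (2.29 ± 0.12). Mature NK cell genes fell in 14 of 18 and rose in 1, in each genotype (adjusted p = 8.3e-16 and 2.07e-22). Of 26 trafficking receptors and integrins 20 fell in WT and 19 in KO, with 1 that rose in each (adjusted p = 0.0166 and 0.00461 with an estimated correlation).

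Of 25 adaptors and partner receptors 23 fell and none rose in WT (adjusted p = 1.68e-13, and adjusted p = 0.0542 with an estimated correlation). Tyrobp (DAP12) fell by 1.77 ± 0.14 and Ncr1 (NKp46) by 1.63 ± 0.12. In KO 19 fell and 2 rose (adjusted p = 0.142 with an estimated correlation). Fcer1g itself fell by 1.5 ± 0.26 in WT. In oxidative phosphorylation 37 of 47 genes fell in WT (adjusted p = 2.3e-05, and adjusted p = 0.512 with an estimated correlation) and 14 in KO (adjusted p = 0.549 with an estimated correlation), and none rose in either. Long transcripts rose and short ones fell with IL-15, with medians of 0.526 and −0.538 in WT and 0.239 and −0.263 in KO, and a length correction was not run for IL-15 against naive. Of 35 MYC targets and ribosome biogenesis genes 26 rose and 1 fell in WT, with Myc at 1.69 ± 0.12 and Nolc1 at 1.93 ± 0.15 (adjusted p = 0.117 with an estimated correlation). In KO 23 rose (adjusted p = 0.203 with an estimated correlation). Nutrient transporters and mTORC1 targets gave 14 that rose and 5 that fell of 23 in WT, the transferrin receptor gene Tfrc at 4.23 ± 0.29 (adjusted p = 0.176 with an estimated correlation). Interferon-stimulated genes fell in 27 of 39 and rose in 6 in WT, with Cmpk2 at −1.97 ± 0.16 (adjusted p = 0.0542 with an estimated correlation).

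Cytotoxic granule and death ligand genes parted in WT, with 7 that rose and 17 that fell of 26, a median of −0.66 and a mean of 0.13 (adjusted p = 0.176 with an estimated correlation). Gzmc rose while Gzmm fell by 3.44 ± 0.24 and Nkg7, a granule membrane protein gene, by 1.98 ± 0.15. Of 20 cytokine and chemokine genes 9 rose and 2 fell in WT, with Ccl1 at 7.44 ± 0.57 and Ccl5 at −2.33 ± 0.18 (adjusted p = 0.176 with an estimated correlation). Of 23 quiescence genes and cell cycle inhibitors 4 rose and 12 fell in each genotype (adjusted p = 0.0542 in WT and 0.0615 in KO with an estimated correlation). Inhibitory receptors and dysfunction genes gave 13 that rose and 4 that fell of 23 in WT, where Tnfrsf9 (4-1BB) rose by 1.91 ± 0.15 and Klrg1 fell by 2.5 ± 0.15 (adjusted p = 0.319 with an estimated correlation). The IL-15 and STAT5 list had 12 that rose and 14 that fell of 33 in WT, with Irf4 at 3.56 ± 0.25. Platelet genes, which mark other cells, were also lower: Ppbp had no read under IL-15 and was at least 308-fold lower in WT and at least 393-fold lower in KO. Summed platelet markers went from 26.9 to 1.01 CPM in WT and from 41.3 to 1.58 CPM in KO.

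**Figure D3:**
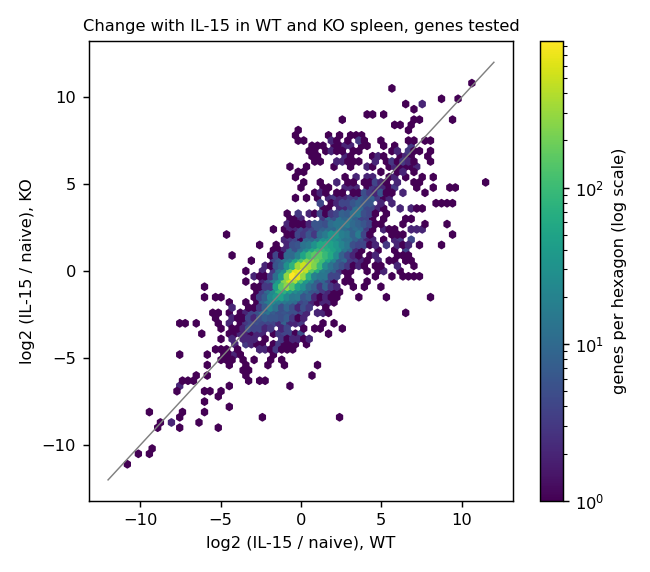
Each cell of the plot counts tested genes by their log2 change under IL-15 in WT (across) and in KO (upward). The correlation over 13344 genes was 0.789 and the slope of KO on WT 0.768.

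The KO effect differed between naive and IL-15-treated spleen for 205 genes, 63 with a higher KO effect under IL-15 and 142 with a lower one. The differences were 4.84 ± 0.80 log2 units for Ccl6 (adjusted p = 0.00507), 3.50 ± 0.35 for Fcgr2b (adjusted p = 9.91e-05), 2.5 ± 0.34 for Hsph1 and 1.93 ± 0.39 for Fcer1g. They were 1.61 ± 0.23 for Hspa8, 1.58 ± 0.22 for Stip1, 1.52 ± 0.25 for Dnaja1 and 1.53 ± 0.23 for Dynll1, a dynein light chain gene. Other genes went the opposite way: Myh9, the nonmuscle myosin heavy chain gene, at −2.43 ± 0.36 (93.8 ± 38.4 CPM in naive WT and 577 ± 203 in naive KO), Tln1 (talin) at −1.87 ± 0.35 and Ccdc88c at −2.08 ± 0.34. The cold-inducible Cirbp stood at −2.00 ± 0.36 and Rbm19 at −1.96 ± 0.36. Cish, a STAT5 target that restrains IL-15 signalling, differed by 1.27 ± 0.26 (adjusted p = 0.0206). For Fcer1g, the deleted gene, the difference rests on residual KO reads. These stood at 3.77 CPM in naive spleen and 5.65 CPM under IL-15, against 730 and 274 CPM in WT.

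Smaller differences passed for Klre1 (0.77 ± 0.19), Ccnd3 (0.58 ± 0.13), Slc7a1 (−0.74 ± 0.18), Nolc1 (−0.94 ± 0.21) and Bach2 (−0.96 ± 0.23). In the adaptor list 3 of 25 had a higher KO effect under IL-15 and none a lower one (adjusted p = 3.87e-06, and adjusted p = 0.668 with an estimated correlation). These were Klre1, Fcgr2b and the deleted Fcer1g. None of 47 oxidative phosphorylation genes passed (adjusted p = 0.00125, and adjusted p = 0.868 with an estimated correlation). Of 24 named genes 16 kept their call in every alternative. With each of 16 libraries left out in turn, the call ended 15 times for Klre1, 14 times for Slc7a1, 11 times for Bach2 and Nolc1, 10 times for Ccnd3 and 4 times for Cish. The largest adjusted p was 0.139 for Klre1, 0.135 for Slc7a1, 0.116 for Bach2 and 0.079 for Nolc1 (without KO IL15 replicate 4), 0.1 for Ccnd3 (without WT IL15 replicate 4) and 0.0597 for Cish (without WT naive replicate 2). The length and GC correction ended the call for Klre1 (0.164) and Slc7a1 (0.175), fitting all 24 libraries for Klre1 (0.0511) and no filter for Slc7a1 (0.0596). A block by replicate number ended it for Klre1 (0.081), Slc7a1 (0.0816), Bach2 (0.0555) and Ccnd3 (0.0575). The counts were 301 higher and 413 lower without WT IL15 replicate 2 and 28 higher and 56 lower without WT IL15 replicate 4, and DESeq2 gave 215 higher and 471 lower.

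NK cell libraries of tumour-bearing lung, set against naive spleen, carried high transcripts of immediate early genes, NR4A receptors and inflammatory cytokines in both genotypes. Tissue, tumour and any difference in preparation between lung and spleen cannot be told apart here. No lung without tumour was among the samples. Long and short transcripts had medians of 0.453 and −0.298 in WT and 0.204 and −0.094 in KO, and a length correction was not run for lung against spleen. Nr4a1, an orphan nuclear receptor gene induced by receptor signalling, rose by 5.14 ± 0.19 in WT (n = 4 and 4, adjusted p = 6.47e-16) and 4.50 ± 0.19 in KO. Nr4a2 rose by 5.02 ± 0.26 and 5.18 ± 0.27, and Tnfaip3 (A20), which restrains NF-κB, by 4.87 ± 0.19 and 4.31 ± 0.19. Ifng rose by 2.94 ± 0.19 and 2.16 ± 0.19, the chemokine gene Ccl3 by 3.14 ± 0.19 and 2.49 ± 0.19, and Vegfa by 4.85 ± 0.26 and 4.15 ± 0.25. Cxcr3 fell by 2.35 ± 0.18 and 2.08 ± 0.18 and Ncr1 by 1.27 ± 0.11 and 1.07 ± 0.11. In WT 4171 genes were higher and 2850 lower of 14275 tested, and in KO 3468 and 2581; 2885 were higher in both (1013.3 if independent) and 1920 lower in both (515.3 if independent).

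Of 33 immediate early and heat shock genes 31 rose and 1 fell in WT, and 29 rose and none fell in KO (adjusted p = 2.29e-35 and 6.01e-41). Cytokine and chemokine genes rose in 15 of 21 and fell in 2 in WT, and rose in 13 and fell in 1 in KO (adjusted p = 0.0308 and 0.0254 with an estimated correlation). Of 20 TGFβ response genes 13 rose and 2 fell in WT, and 12 rose and 3 fell in KO (adjusted p = 0.0189 and 0.0144 with an estimated correlation). The signalling regulator Rgs16 rose by 5.21 ± 0.26 and Tgif1 by 3.13 ± 0.14 in WT. Quiescence genes rose in 14 of 24 and fell in 4 in WT, with Klf4 at 4.48 ± 0.24 (adjusted p = 0.0308 with an estimated correlation). IL-15 and STAT5 genes rose in 15 of 33 and fell in 3 in WT, with Socs3 at 2.87 ± 0.18 and Irf8 at 2.27 ± 0.12 (adjusted p = 0.0308 with an estimated correlation). Inhibitory receptors and dysfunction genes rose in 14 of 25 and fell in 4 in WT (adjusted p = 0.0849 with an estimated correlation).

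Adaptors and partner receptors fell in 19 of 26 and rose in 3 in WT, Klrb1c (NK1.1) at −1.38 ± 0.11 (adjusted p = 0.163 with an estimated correlation). Interferon-stimulated genes fell in 21 of 41 and rose in 5, Ifi47 at −1.79 ± 0.11 (adjusted p = 0.0986 with an estimated correlation). MYC targets rose in 20 of 35 and fell in 2 in WT (adjusted p = 0.000583, and adjusted p = 0.299 with an estimated correlation). Of 48 mitotic and S phase genes 6 rose and 23 fell in KO, with Nusap1 at −1.61 ± 0.23 (adjusted p = 0.000555, and adjusted p = 0.284 with an estimated correlation), against 9 that rose and 13 that fell in WT. Of 12 Ly49 genes 2 rose and 7 fell in WT, with a median of −0.55 and a mean of 0.34. Genes of lung cells rose with these groups: Cldn5, of endothelial junctions, had no read in WT spleen and was at least 825-fold higher in WT lung. The airway gene Scgb1a1, at 139 ± 160 CPM in KO lung, was at least 3.94e+03-fold higher there, a call that ended with voom. Dct, a melanocytic enzyme gene, was at least 400-fold higher in KO lung than in KO spleen. Of the named genes 79 of 80 kept their call in every alternative in WT and 80 of 84 in KO.

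**Figure D4:**
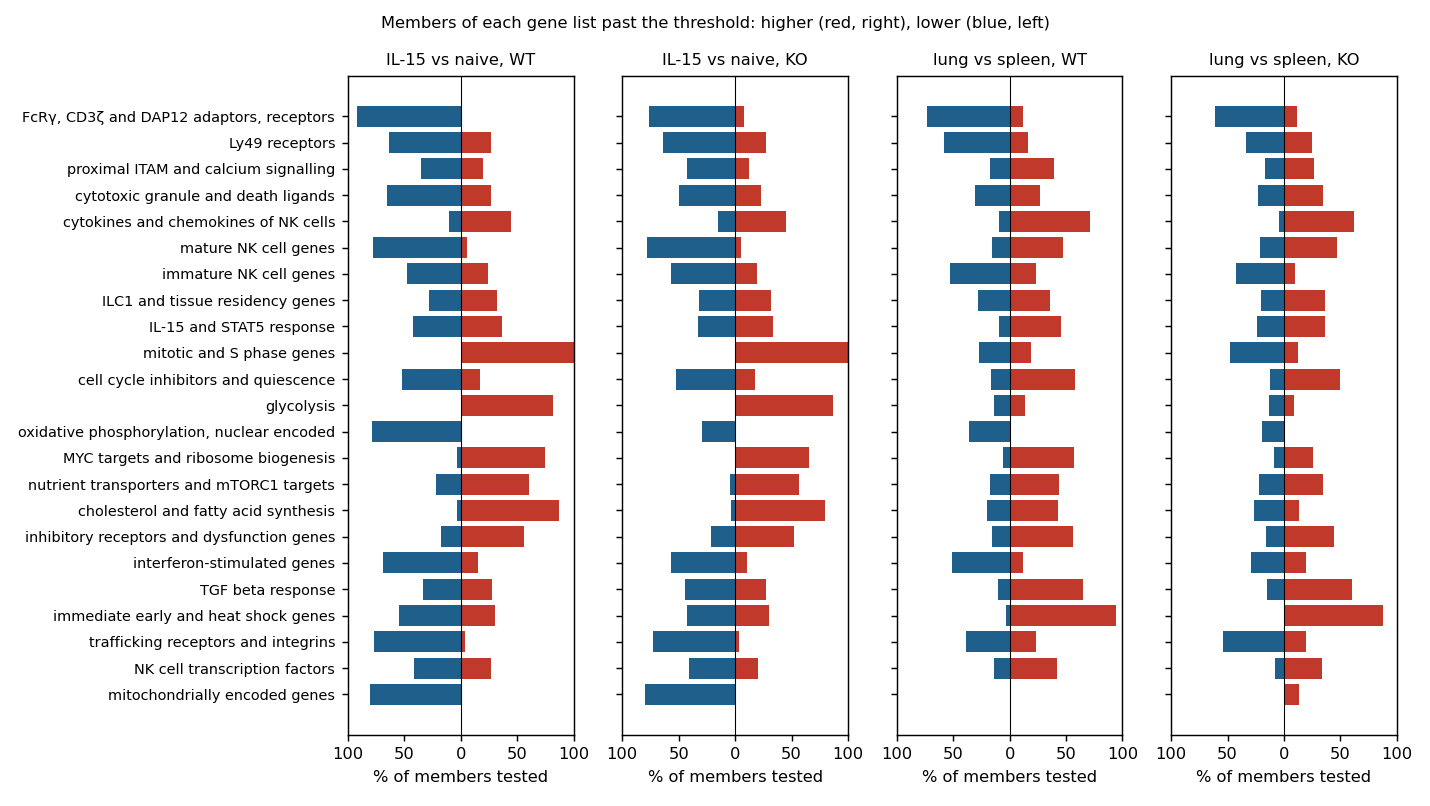
Bars give the percent of tested members of each gene list that were higher (right) or lower (left) with IL-15 or in lung, in WT and KO. All 48 mitotic and S phase genes rose with IL-15 in both genotypes, and 31 of 33 immediate early and heat shock genes rose in WT lung.

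The KO effect differed between lung and naive spleen for 164 genes, 24 with a higher KO effect in lung and 140 with a lower one. It was higher in lung by 4.20 ± 0.53 for Ccl6 (adjusted p = 0.000196), 2.14 ± 0.35 for Fcer1g, 2.65 ± 0.48 for Ifi204 and 0.95 ± 0.15 for Sh2d1b1 (EAT-2A). It was lower in lung for Myh9 (−2.43 ± 0.35, adjusted p = 0.00171), the plectin gene Plec (−1.92 ± 0.38), Rbm19 (−1.98 ± 0.34), Atp10d (−1.84 ± 0.38) and Nolc1 (−1.08 ± 0.20). Others passed more narrowly: Gzmk (2.14 ± 0.45), Cd63 (1.98 ± 0.47), Oas3 (1.49 ± 0.32), Cish (1.01 ± 0.26), Pyhin1 (0.95 ± 0.24) and Xaf1 (0.85 ± 0.20). On the lower side were Fcgr2b (−1.19 ± 0.30), Rrp12 (−1.36 ± 0.30), Utp20 (−0.92 ± 0.20), Fasn (−0.92 ± 0.22), Smad7 (−0.89 ± 0.21) and Tnfrsf9 (−0.85 ± 0.20). The Fcer1g value rests on residual KO reads, at 3.77 CPM in naive spleen and 14.3 CPM in lung.

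Of 35 MYC targets 5 had a lower KO effect in lung and none a higher one (adjusted p = 2.57e-06, and adjusted p = 0.434 with an estimated correlation). In lung 2 of 41 interferon-stimulated genes had a higher one (adjusted p = 3.96e-05, and adjusted p = 0.434 with an estimated correlation). In the adaptor list 1 of 26 was higher and 1 lower (adjusted p = 9.05e-06, and adjusted p = 0.434 with an estimated correlation). These were the deleted Fcer1g and its neighbour Fcgr2b. Of 28 named genes 10 kept their call in every alternative. With each of 16 libraries left out in turn, it ended 13 times for Cish and Fcgr2b, 11 times for Xaf1, Fasn, Pyhin1 and Smad7, 10 times for Tnfrsf9, 8 times for Cd63, 6 times for Rrp12, 5 times for Utp20, 3 times for Oas3 and 2 times for Gzmk. The largest values came without WT naive replicate 3 for Gzmk (adjusted p = 0.0606), Xaf1 (0.105), Fasn (0.105), Utp20 (0.0606) and Tnfrsf9 (0.0926), and without WT naive replicate 2 for Cish (0.116). They came without WT lung replicate 3 for Pyhin1 (0.102) and Rrp12 (0.0773), without KO lung replicate 2 for Cd63 (0.0918) and without KO lung replicate 4 for Oas3 (0.0589), Fcgr2b (0.099) and Smad7 (0.0832). Voom ended the call for Cd63 (0.0566) and Tnfrsf9 (0.0755), leaving out the shallow libraries for Tnfrsf9 (0.0517), no filter for Fcgr2b (0.0543), DESeq2 size factors for Cish (0.0532) and the length and GC correction for Xaf1 (0.0518). A block by replicate number ended it for Cd63 (0.0506), Cish (0.0676), Fasn (0.0567) and Fcgr2b (0.0623). Without WT lung replicate 1 the counts were 160 higher and 410 lower, and without WT naive replicate 3 they were 9 higher and 64 lower.

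Markers of other cell types were summed in each library. In naive spleen the summed markers of NK cells stood at 1.74e+04 CPM in KO and 2.16e+04 in WT, and of plasma cells at 80.9 and 123 (mostly Xbp1). Those of dendritic cells stood at 877 and 658 (mostly Itgax), of endothelium at 112 and 67.4 (mostly Pecam1) and of basophils or mast cells at 0.889 and 7.86. Each of these had exact p = 0.0286 and adjusted p = 0.184 over 45 tests. As 0.0286 is the smallest exact p possible, the adjusted value could pass only if far more of the 45 tests had reached it. Naive T cell markers stood at 349 and 288 CPM and B cell markers at 194 and 195. Monocyte or macrophage markers stood at 238 and 160 CPM, mostly Ly6c2 (226 and 150), which the mature NK cell list also held. Neutrophil markers stood at 1.46 and 1.44 and erythroid markers at 1.74 and 1.59. In lung, B cell markers stood at 177 CPM in KO and 125 in WT (exact p = 0.0286, adjusted p = 0.184), and fibroblast or stroma markers at 20.8 and 20. Monocyte or macrophage markers stood there at 747 ± 206 and 493 ± 107 (exact p = 0.0857, adjusted p = 0.297). Ly6c2 held 369 and 367 CPM of these sums, so their difference lay in the other markers of the list. Lung epithelium markers stood at 188 ± 180 and 70.1 ± 29.5, melanocytic markers at 32.1 ± 20.4 and 10.4 ± 9.88, and ILC2 or ILC3 markers at 0.999 and 1.35. Across all 24 libraries Xist stood between 0.0907 and 10.5 CPM and Ddx3y between 62.6 and 130 CPM.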

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

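The splits of the samples were set before the data were examined; the tests of the 3 patterns weighed below were chosen only after the results were seen.

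In KO against WT, the genes called under IL-15 lay mostly near Fcer1g, and 14 genes were called in all 3 states. Chance clustering was tested by counting windows of the same width on other chromosomes that held as many called genes: 0 of 12534 did. Only 5 called genes lay outside the window of Fcer1g, which held 12, so no other window could have held as many. The count thus restates the clustering that prompted the test and adds no separate evidence against chance. DNA of another strain carried along with the targeted allele could give such a pattern. As a test, 86.7% of the nearby genes called under IL-15 or in lung and tested in all 3 states kept 1 sign (13 of 15, all but Sh2d1b1 and Fcgr2b). This cannot tell it from other local causes, as no sequence variants were analysed here. A loss of FcRγ acting without regard to position was the biological alternative. Of the genes called in all 3 states besides Fcer1g, 61.5% lay within 10 Mb (8 of 13, 95% interval 31.6 to 86.1) against 1.18% of tested genes. These genes are by definition among those called under IL-15, whose place near Fcer1g prompted the test. The share thus restates that clustering and adds no separate evidence on this alternative.

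Long transcripts were higher in naive KO, with a rank correlation of 0.365 between change and exon length. The difference between long and short transcripts varied within groups by up to 1.366 log2 units (IL-15 WT), so a length trend that varies from library to library may account for part of it. Within the naive groups that range was 0.390 in WT and 0.491 in KO, below the KO minus WT difference of 0.673 (exact p = 0.0286), so this does not settle the matter. The shallow library KO naive replicate 1 was not the source, as the correlation was 0.401 without it. The biological alternative is the genotype itself, with differences of 0.120 under IL-15 (exact p = 0.8) and 0.256 in lung (exact p = 0.657). The rank correlation was 0.326 in lung KO against WT and 0.323 for IL-15 in WT. The IL-15 value uses the same naive WT libraries, the group with the lowest mean (−0.767). In lung, WT replicate 1 stood at −0.926, with the other WT libraries at 0.242 to 0.405 and KO at 0.077 to 0.422. The lung correlation was not computed without it. These 2 correlations thus do not show whether the trend was peculiar to the naive libraries.

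Cytosolic chaperone genes were lower in naive KO, with a median of −0.664 over a list drawn up after the result was seen. A length and GC trend left the median at −0.536 and the call for 25 genes instead of 30, and leaving out KO naive replicate 1 left it at −0.594, so neither accounts for it. Handling of the cells that differed with genotype could lower chaperones and raise cold-inducible transcripts together: Cirbp rose by 1.96 in naive KO, which cannot tell handling from genotype, as the labels give no handling order. In lung the chaperones fell by a median of 0.540 log2 units with Cirbp at 0.30, below its naive value (adjusted p of the difference 0.00922), so the fall of chaperones there did not come with a rise of Cirbp of the naive size. The biological alternative, an effect of FcRγ in naive cells, was not told apart from it either.

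Chance would mark about 1 in 20 groups of 4 as holding a library far from the others, or 8.5 of the 169 groups examined, and 19 were marked. Total counts stood apart in WT IL15 replicate 2 (21.18 M against 29.79 to 30.55) and WT lung replicate 1 (9.77 against 24.73 to 26.98), and the mitochondrial share in WT IL15 replicate 3 (2.78% against 1.76 to 1.88) and KO lung replicate 2 (10.73% against 8.49 to 8.83). The difference of long and short transcripts stood apart in WT naive replicate 4 (−0.482 against −0.872 to −0.842) and WT lung replicate 1 (−0.926 against 0.242 to 0.405). Summed markers stood apart for T cells in KO naive replicate 1 (312 CPM against 358 to 364), B cells in WT IL15 replicate 2 (125 against 139 to 142), monocytes in KO IL15 replicate 1 (35.4 against 47.3 to 48.6), basophils or mast cells in WT naive replicate 4 (17.4 against 3.67 to 5.71) and erythroid cells in WT naive replicate 2 (2.55 against 1.15 to 1.35). They also did for fibroblasts in KO naive replicate 1 (4.34 against 0.0385 to 0.759) and ILC2 or ILC3 in WT IL15 replicate 2 (0.712 against 1.84 to 1.94). Single genes stood apart for Fcer1g (321 CPM against 253 to 261), Spp1 (611 against 486 to 504) and Cma1 (8.24 against 4.02 to 4.41) in WT IL15 replicate 2. So did Hsph1 in KO lung replicate 1 (239 against 115 to 132), Il7r in WT lung replicate 2 (30.6 against 22.1 to 23.4) and Ccl6 in WT lung replicate 3 (5.39 against 12.2 to 12.8).

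The KO effect differed between naive and IL-15-treated spleen in 205 genes by the interaction test, with differences of 4.84 for Ccl6, 3.50 for Fcgr2b, 2.5 for Hsph1, 1.93 for Fcer1g, 1.61 for Hspa8, 1.58 for Stip1, 1.53 for Dynll1, 1.52 for Dnaja1, 1.27 for Cish, 0.77 for Klre1 and 0.58 for Ccnd3. Differences below 0 were −0.74 for Slc7a1, −0.94 for Nolc1, −0.96 for Bach2, −1.87 for Tln1, −1.96 for Rbm19, −2.00 for Cirbp, −2.08 for Ccdc88c and −2.43 for Myh9. Between naive spleen and lung it differed in 164 genes, with 4.20 for Ccl6, 2.65 for Ifi204, 2.14 for Fcer1g and for Gzmk, 1.98 for Cd63, 1.49 for Oas3, 1.01 for Cish, 0.95 for Sh2d1b1 and for Pyhin1 and 0.85 for Xaf1. Differences below 0 there were −0.85 for Tnfrsf9, −0.89 for Smad7, −0.92 for Fasn and for Utp20, −1.08 for Nolc1, −1.19 for Fcgr2b, −1.36 for Rrp12, −1.84 for Atp10d, −1.92 for Plec, −1.98 for Rbm19 and −2.43 for Myh9. Fcer1g is the deleted gene, and its differences rest on residual KO reads.

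With other splits of the same libraries, the real grouping ranked 1 of 35 in KO against WT: 2705 genes against at most 17 in naive spleen, 18 against 0 under IL-15 and 82 against 2 in lung. It also ranked 1 of 35 for IL-15 in WT (6994 against 927) and KO (5564 against 0) and for lung against spleen in WT (7021 against 2547) and KO (6049 against 305), so a chance result can be excluded at 1 in 35 in each. For the interactions the real grouping ranked 3 of 100 under IL-15 (205 genes, at most 899 in another split) and 4 of 100 in lung (164 genes, at most 1195). The highest of these splits exchange the genotype labels of replicates 1, 3 and 4 in the IL-15 or lung libraries and call several times the real count. These splits keep the naive genotype labels, so the structure they follow holds the naive KO effect. In each interaction only 3 other splits kept those labels. Of these, 2 under IL-15 and 3 in lung called at least as many genes as the real one. The 96 splits that mixed the naive labels called at most 1 gene under IL-15 and 12 in lung. The ranks out of 100 thus rest on splits that break the naive KO effect. Among splits that kept the naive labels the real grouping did not stand out, but these 3 splits hold the naive KO effect themselves. The splits thus do not bear out the interaction counts, and so few of them cannot decide for or against the counts.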

How the results depend on the processing

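Of 8713 values for 499 named results under the alternatives, 8225 kept their direction and their side of the threshold, 485 no longer passed, 2 newly passed and 1 reversed: Gzma in naive KO against WT, at 0.016 with the length and GC offset. That offset left 2019 calls in naive KO against WT (1521 of the 2705 kept, 62 with the sign changed) and gave 95 lower in lung KO against WT, 101 higher for the IL-15 interaction and 41 higher and 230 lower for the lung interaction. Of all genes the naming rule gave that passed, those that kept their call everywhere were 55 of 74 in naive KO against WT, 13 of 18 under IL-15 and 17 of 28 in lung. They were 81 of 81 for IL-15 in WT, 80 of 83 in KO, 16 of 24 for the IL-15 interaction, 79 of 80 for lung in WT, 80 of 84 in KO and 10 of 28 for the lung interaction. Of 225 list tests, 147 kept their side of the threshold with an estimated correlation and 78 did not. Fitting the compared groups alone gave 787 lower in naive KO against WT. DESeq2 gave 20 higher under IL-15, 162 higher and 154 lower in lung, 215 and 471 for the IL-15 interaction and 92 and 428 for the lung interaction. Voom with library weights gave 30 higher and 24 lower under IL-15, 128 and 140 in lung, 502 and 818 for the IL-15 interaction and 104 and 398 for the lung interaction. No filter gave 68 higher in lung, and fitting all 24 libraries gave 18 higher under IL-15 and 97 and 271 for the IL-15 interaction. Leaving out the shallow libraries, added after the data were seen, gave 147 higher and 359 lower for the lung interaction. The correlation of the IL-15 change between genotypes was 0.879 over genes called in WT and 0.883 over those called in KO. For each of these changed results the cause was not tested.

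With 1 library left out in turn, calls in KO against WT ranged from 942 to 1503 higher and 755 to 1226 lower in naive spleen (lowest without WT naive replicate 3), 7 to 10 higher under IL-15, and 16 to 251 higher and 25 to 197 lower in lung (highest without WT lung replicate 1). The IL-15 interaction ranged from 28 to 301 higher and 54 to 413 lower (highest without WT IL15 replicate 2), the lung interaction from 9 to 160 higher and 61 to 410 lower (highest without WT lung replicate 1), and the correlation from 0.736 to 0.804. Replicate numbers gave no clear sign of pairing, as deviations of same-numbered libraries correlated at no more than 0.275 and often below 0 in KO against WT. For IL-15 against naive, libraries that share a number in their names correlated at −0.059 to 0.075 in WT and −0.066 to 0.203 in KO. This does not settle whether they share animals. Of 8 libraries in each comparison, 1 to 4 correlated best with their own replicate number, with 4 both in naive KO against WT and for IL-15 in WT. A block by the number in the library name, over the 6 libraries of a genotype that share one, called 2632 and 2399 for IL-15 in WT and 2232 and 1934 in KO. With a block by replicate number the fits called 1345 higher and 1113 lower in naive KO against WT, 8 and 6 under IL-15, and 30 and 32 in lung. They called 3483 and 3387 for IL-15 in WT, 2754 and 2644 in KO, 45 and 104 for the IL-15 interaction, 4105 and 2883 for lung in WT, 3436 and 2506 in KO and 19 and 118 for the lung interaction. On simulated data 12.3 to 37.9% of changes of 1.5-fold were recovered.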

Other observations

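These lists were drawn up after the data were seen, so no list test is given for them. Of 45 cytosolic chaperone and cochaperone genes 30 fell and 1 rose in naive KO against WT. Stip1 stood at −1.55 ± 0.16, Fkbp4 at −1.40 ± 0.16, Hsp90aa1 at −1.31 ± 0.16, Chordc1 at −1.29 ± 0.16 and Hsp90ab1 at −0.88 ± 0.10. In lung 16 fell and none rose, with Ahsa1 at −1.03 ± 0.11, and under IL-15 none of the 45 passed. The KO effect on 14 of them was higher under IL-15 than in naive spleen. Of 8 mitochondrial chaperones 3 fell and none rose in naive KO, and of 16 chaperones of the endoplasmic reticulum 3 fell and 1 rose. In lung KO 2 of the mitochondrial chaperones fell, and none of the 16 of the endoplasmic reticulum passed.

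The cold-inducible RNA binding proteins Cirbp (1.96 ± 0.26, adjusted p = 0.000102) and Rbm3 (0.90 ± 0.12, adjusted p = 0.000129) were both higher in naive KO. In lung KO, where chaperones fell, they stood at 0.30 ± 0.11 (adjusted p = 0.349) and 0.19 ± 0.13 (adjusted p = 0.612), and the KO effect on both was lower in lung than in naive spleen (adjusted p = 0.00922 and 0.0385). Of 13 tested circadian clock genes 2 were higher in naive KO and none lower, Nr1d1 at 4.47 ± 1.03 and Per1 at 0.78 ± 0.19. Without WT lung replicate 1, the median change of the 15 mitochondrially encoded genes in lung KO against WT was 1.03, and 14 of them were higher.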
